A study of Mus musculus with 2 samples.

How the data were processed

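The series holds polyA mRNA sequencing of testis from 1 adult male C57BL/6J mouse, an inbred laboratory strain, aged 10 weeks. Per the labels, RNA was extracted with a kit for fatty tissue (RNeasy Lipid Tissue Mini Kit), and the library size range was 350 to 450 bases. Both libraries come from 1 biological replicate and are technical replicates 1 and 2. Per the labels, the technical replicate made later, in 2015, was replicate 2. There is 1 group and no second condition, so every value describes this animal, and n is 2 technical libraries wherever an SD is given.

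For each library the authors deposited a table of genes and a table of transcripts. Per the deposited notes, both were quantified from alignments to the transcriptome on the mm10 assembly with annotation release M4, separately for each library. The aligner and the quantification program are not given in the sources used here. The authors deposited expected counts, which are estimated reads per gene or transcript and need not be whole. They also deposited TPM (transcript abundance scaled for effective length and depth) and FPKM (fragments scaled for length and depth). The transcript tables deposited by the authors give, as a percent, each transcript's share of its gene's level. The posterior mean TPM, the posterior SD of each count and an interval for each TPM, also deposited by the authors, were used in checks, and the level of that interval is not stated in the files. A read that fits several near-identical genes is divided between them in such estimates, so values of multicopy genes and pseudogenes are uncertain.

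The gene tables have 69691 entries. Of these, 43346 are genes, 26248 carry purely numeric identifiers and 97 are spike-in controls. The expected counts summed to 31995377 in replicate 1 and 20675551 in replicate 2. The spike-in controls held 0 counts in both libraries. Names, biotypes and positions came from GENCODE release M21 on the same assembly (GRCm38, mm10), matched by identifier without its version, for 42462 of the 43346 genes. The 884 unmatched genes held 0.306% of the expected counts in replicate 1 and 0.242% in replicate 2. Coordinates are 1-based positions on mm10. GC content is that of each gene's most abundant transcript, from the M21 transcript sequences, and was known for 99.00% of the tested genes. In 76.3% of the tested genes that transcript had the same length in M21 as in the deposited table.

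A gene counted as detected at 1 TPM or more in both libraries. Expected counts were rounded and compared between the libraries with an exact two-sided conditional binomial test per gene. Library sizes were scaled by TMM in edgeR 4.0.16 (factors 0.904 and 1.11). P-values were adjusted by Benjamini-Hochberg over the 18581 genes with a mean of 10 counts or more. A gene was called at an adjusted p under 0.05 and a ratio of 2 or more. This test compares the reads of these 2 libraries, not conditions or animals. Log2 ratios are replicate 2 over replicate 1, with 0.5 added to each count. A gene list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression, as a description without a p-value. A germ cell form and its somatic relative were compared by the ratio of their TPM within a library. That ratio was called different from 1 if the exact (Clopper-Pearson) 95% interval on length-scaled counts excluded 1 in both libraries. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which is 0.0938 CPM in replicate 1 and 0.145 in replicate 2.

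The gene lists, the pairs, the isoform genes, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 20 named nuclear genes of highest mean TPM, the 4 highest members of each list by mean TPM (2 for other organs), all pairs and isoform genes, the 8 largest ratios in each direction among called genes with a mean of 100 counts or more, and the 5 X-linked and 5 Y-linked genes of highest mean TPM. Of the genes this rule picked, 1 is not reported here. The alternatives covered detection limits, FPKM, posterior mean TPM, each library alone, other scalings (plain totals and DESeq2 1.42.0 size factors), other count filters and ratio limits, and an edgeR exact test with an assumed biological coefficient of variation of 0.1. The filter that keeps pseudogenes out of the ribosomal list at first removed every gene named Rps, and it was corrected after the data were seen. Corrections for GC content were added after seeing the data. In them, each gene's expected ratio was set to the median ratio of genes of similar GC content, from 100 bins of equal gene number. Similarity of chromosome 1 pseudogenes to mitochondrial genes came from BLAST 2.17.0. Other computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

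The gene test was tested on simulated counts drawn from the pooled profile at the real library sizes, with 200 genes changed. Over 18368 simulated genes it recovered 40.3% of genes changed 2-fold, which is the limit itself, 97.01% of those changed 4-fold and 98.4% of those changed 8-fold, with 1 false call. With a GC trend added and left uncorrected, it recovered 62.5% of 4-fold changes over 18458 genes and called 11490 genes (62.9% of the unchanged ones) that differed by the trend alone. With the trend corrected, it recovered 98.4% of 4-fold changes over 18280 genes, with 17 false calls. The simulated genes followed an exact linear trend with counting error only. The SD of the real log2 ratios was still 1.12 after the GC correction. The number of false calls in the simulation therefore does not carry over to the real genes. For the list comparison, 7.50% of 200 unshifted lists and all 20 lists shifted by 1 on the log2 scale fell outside the central 95% of random lists.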

Results

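PolyA mRNA was sequenced from the testis of 1 adult male mouse in 2 technical replicate libraries. The tables hold 31995377 expected counts in replicate 1 and 20675551 in replicate 2. The libraries were not copies of each other. A chi-square comparison of their counts gave 577 per degree of freedom over 18581 genes, where sampling noise alone gives about 1. Levels are therefore given for each library, in the order replicate 1 and replicate 2. No value here has a replicate across animals.

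13778 genes were detected at 1 TPM or more in both libraries, and most were protein-coding (11725 of 21474 annotated, 54.6%). Long intergenic noncoding RNAs contributed 543 genes, antisense genes 486 and processed pseudogenes 293. Another 2937 genes passed 1 TPM in replicate 2 alone and 833 in replicate 1 alone. The median transcript GC content was 56.3% for the former and 42.7% for the latter.

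By mean TPM, genes that package sperm DNA were among the most abundant nuclear genes, a rank that rests on replicate 2. In replicate 1 Crisp2, Meig1, Fabp9 and Smcp each stood above all 4 of them. Protamine 2 (Prm2, ENSMUSG00000038015.6, chromosome 16, 10791380 to 10796134 on mm10) reached 45.4 and 15928 TPM. Protamine 1 (Prm1, ENSMUSG00000022501.5, chromosome 16, 10796326 to 10805839) reached 3011 and 10087 TPM. The transition proteins, which replace histones before the protamines, stood at 1008 and 9611 TPM for Tnp1 (ENSMUSG00000026182.6, chromosome 1, 73015074 to 73015909) and 468 and 9012 TPM for Tnp2 (ENSMUSG00000043050.7, chromosome 16, 10787936 to 10788660). The sperm proteins Crisp2 and Smcp reached 6903 and 2887 TPM and 3836 and 3821 TPM, respectively. Meig1, needed for spermiogenesis, reached 5574 and 3429.8 TPM, and the fatty acid binding protein Fabp9 4601 and 2599.5 TPM. The sperm lactate dehydrogenase Ldhc reached 2850.2 and 4131 TPM, and the glutathione transferase Gstm5 2548 and 3295 TPM. Gm3448, Spata4, Fhl4 and the ubiquitin gene Ubb completed the protein-coding genes among the 20, at 7920.1 and 3101 TPM, 3799 and 1525 TPM, 3287 and 1890.4 TPM and 115 and 4692 TPM.

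The remaining 6 of these 20 genes were pseudogenes on chromosome 1 that are copies of mitochondrial genes: Gm28661, Gm10925, Gm28437, Gm29216, Gm10222 and Gm28438. Gm28661 (chromosome 1, 24614885 to 24615565) matched mt-Co2 over 681 bases with 0 mismatches, and its 236951 estimated reads in replicate 1 carried a posterior SD of 44053. Reads that fit both a copy and its mitochondrial gene are divided between them, so their separate levels are uncertain.

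Transcripts of the 13 mitochondrial mRNAs made up 12.6% of all TPM in replicate 1 and 2.62% in replicate 2 (7.60% ± 7.05, SD, n = 2 technical libraries). With their 7 chromosome 1 copies they made up 20.4% and 5.26%. By mean TPM, the 4 highest were mt-Atp8 (43146 and 9526 TPM), mt-Co1 (27197 and 6559 TPM), mt-Nd1 (11097 and 2462 TPM) and mt-Co2 (9375 and 475 TPM). In replicate 2 alone mt-Co2, whose reads are divided with Gm28661, was not among the 4 highest and lay below mt-Nd4 (1330 TPM). The transcript of mt-Atp8 has 204 bases, below the labelled size range, and effective lengths of 37.8 and 42.8, so its TPM is uncertain. Fragments shorter than that range were counted too, since the 348 base transcript of mt-Nd3 had effective lengths of 163 and 171. The 10 most abundant genes held 15.7% and 7.05% of all TPM, the top 100 held 35.1% and 21.5%, and the top 1000 held 64.4% and 54.7%. Per read, as a share of expected counts averaged over both libraries, the mitochondrial mRNAs held 3.43%. The 10 genes with the largest shares of expected counts, ranked anew, held 4.996%.

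Genes of the later germ cell stages were expressed above most protein-coding genes. The median of the elongating spermatid list lay at percentile 99.7 of protein-coding genes, and all 18 of its members were detected. Its summed level was 14695 and 64861 TPM, and Prm2, Prm1, Tnp1 and Tnp2 were highest by mean TPM. The round spermatid list stood at percentile 94.8, with 17 of 18 members detected. Its highest members were the transcription factor Crem (606 and 425 TPM), the acrosomal genes Zpbp2 (471 and 333 TPM) and Acrv1 (388 and 372 TPM), and Spaca1 (503 and 245 TPM). The late spermatocyte list stood at percentile 92.6 with all 12 members detected. It was led by Ldhc, the phosphoglycerate kinase Pgk2 (1294 and 1045 TPM), Tcp11 (31.2 and 2131 TPM) and the TBP relative Tbpl1 (812 and 391 TPM). Members are ranked by mean TPM here and for the other lists, and the order differed between the libraries. In replicate 1 alone Prm2, Tnp1, Tnp2 and Tcp11 were not among the 4 highest of their lists. In replicate 2 alone Spaca1 and Tbpl1 were not.

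The meiotic prophase list stood at percentile 82.2, with 23 of 24 members detected in both libraries. It was led by the synaptonemal complex gene Sycp3 (807 and 263 TPM), the cohesin gene Stag3 (392 and 337 TPM), Syce1 (305 and 359 TPM) and Hormad1 (502 and 157 TPM). Spermatogonial genes were lower, at percentile 60.4, with 11 of 15 detected. Their highest members were Dmrtb1 (259 and 732 TPM), Uchl1 (7.16 and 70.8 TPM), Id4 (48.7 and 28.2 TPM) and Dmrt1 (22.7 and 16.2 TPM). In the piRNA pathway, which silences transposons in germ cells, 19 of 20 genes were detected, led by Mael (2334 and 1108 TPM), Ddx4 (692 and 319 TPM), Ddx25 (476 and 475 TPM) and Tdrd6 (203 and 374 TPM). Among sperm ion channels and motility genes 16 of the 17 found in the table were detected, with Catsperz at 173 and 651 TPM, Efcab9 at 479 and 228 TPM, Atp1a4 at 221 and 328 TPM and Catsper2 at 268 and 229.9 TPM. The places of Uchl1, Syce1 and Catsperz among the 4 highest rest on replicate 2, and those of Hormad1 and Dmrt1 on replicate 1.

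Leydig and Sertoli cell genes lay above most protein-coding genes, with list medians at percentiles 85.4 and 72.8, and endothelial and macrophage genes lay lower, at 39.1 and 46.9. All 12 Leydig cell genes were detected, with a summed level of 680.3 and 2406 TPM. The hormone gene Insl3 reached 83.2 and 1630.3 TPM. The steroidogenic enzymes Cyp17a1, Hsd3b6 and Hsd3b1, also the top members of the steroidogenesis list, reached 225 and 242 TPM, 97.8 and 121 TPM and 64.1 and 73.8 TPM. Cyb5a, next in that list, was at 57.1 and 67.1 TPM, and 13 of its 14 genes were detected. Sertoli cell genes summed to 1523 and 2055 TPM, with 17 of 20 detected, led by clusterin (Clu, 836 and 1031 TPM), Ctsl (243 and 332 TPM), Aard (194 and 145 TPM) and Amhr2 (2.40 and 172 TPM). Of the Clu level, 751 and 0.28 TPM were assigned to a transcript of 632 bases, so it is uncertain. The Clu counts were 10077 and 22772. Of the peritubular myoid and smooth muscle genes, 5 of 8 were detected. They were led by the smooth muscle actins Actg2 (100.5 and 391 TPM) and Acta2 (9.63 and 58.5 TPM), with Mylk at 12.7 and 13.9 TPM and Tagln at 3.86 and 20.9 TPM. Of the endothelial genes, 4 of 8 were detected, none above 6 TPM. Vwf was at 0.76 and 5.36 TPM, Cdh5 at 0.87 and 3.76 TPM, Kdr at 1.80 and 1.33 TPM and Emcn at 1.66 and 1.12 TPM. Macrophage and leukocyte genes (5 of 11 detected) were led by Lyz2 (15.9 and 30.8 TPM), Mrc1 (29.3 and 13.1 TPM), C1qb (0.46 and 15.99 TPM) and C1qc (0.70 and 11.5 TPM). The places of Amhr2, Hsd3b1 among Leydig genes, Cyb5a, Vwf, Cdh5, C1qb and C1qc rest on the mean and were not reached in replicate 1 alone. In replicate 2 alone Hsd3b1 among Leydig genes, Cyb5a, Kdr and Emcn did not reach theirs.

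Among lists typical of other tissues, the epididymis and red blood cell lists had the highest mean sums. The epididymis list summed to 861 and 444 TPM, most of it from the cystatin Cst8 (797 and 418 TPM), followed by Crisp1 (53.8 and 19.3 TPM), and 4 of 12 members were detected. Hemoglobin and heme genes of red blood cells summed to 27.2 and 328 TPM, with Hbb-bs at 8.28 and 111 TPM, Hba-a2 at 0 and 102 TPM, Hba-a1 at 11.9 and 75.5 TPM and Alas2 at 6.56 and 19.1 TPM. Hba-a1 and Hba-a2 are near-identical copies and share reads. Adipocyte genes summed to 13.9 and 25.8 TPM (Adipoq 7.97 and 9.19 TPM, Fabp4 4.24 and 5.58 TPM). Liver genes summed to 7.20 and 12.1 TPM (Alb 1.34 and 3.64 TPM, Apoa2 1.19 and 2.85 TPM). Brain genes summed to 14.01 and 25.9 TPM (Slc17a7 1.88 and 10.6 TPM). The heart and skeletal muscle list summed to 7.20 and 66.5 TPM, mostly from Tnni3 (5.52 and 56.8 TPM), with Tnnt2 at 1.16 and 7.42 TPM. In the pancreas list 0 of 10 members were detected in both libraries, and its highest members, Cela3b and Cela2a, had 0 and 15 reads and 0 and 9 reads.

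Glycolytic genes summed to 6519.6 and 12802 TPM, with Ldhc, the sperm glyceraldehyde dehydrogenase Gapdhs (483 and 1893 TPM), Pgk2 and Hk1 (1222 and 969 TPM) at the top. Of the Hk1 level, 936 and 69.03 TPM were assigned to a transcript of 254 bases, below the labelled size range, so it is uncertain. The Hk1 counts were 11963 and 40322. Cytosolic ribosomal protein genes summed to 12829 and 32166 TPM, with Rps24 (3147 and 1554), Rpl41 (16.9 and 1292), Rps29 (17.9 and 1257) and Rps27 (609 and 631) at the top. The most abundant Rps27 transcript has 255 bases, below the labelled size range. Rpl41 and Rps29 were not among the 4 highest in replicate 1, and Rps27 was not in replicate 2, where Rpl36 reached 778 TPM. Of 64 replication-dependent histone genes, 7 were detected in these polyA mRNA libraries, which need not hold transcripts without a polyA tail. By mean TPM the highest of the list were Hist2h2aa2 (0.09 and 336 TPM) and Hist2h2aa1 (0 and 173 TPM), neither of which reached 1 TPM in replicate 1, followed by Hist1h2bp (21.6 and 109 TPM) and Hist1h2bc (21.5 and 21.6 TPM). Stress and immediate early genes, which can rise during tissue handling, were led by the chaperone gene Dnajb1 (77.2 and 219 TPM), with Dusp1 at 2.73 and 7.49 TPM, Zfp36 at 2.90 and 5.39 TPM and Jun at 0.97 and 3.79 TPM.

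**Figure D1:**
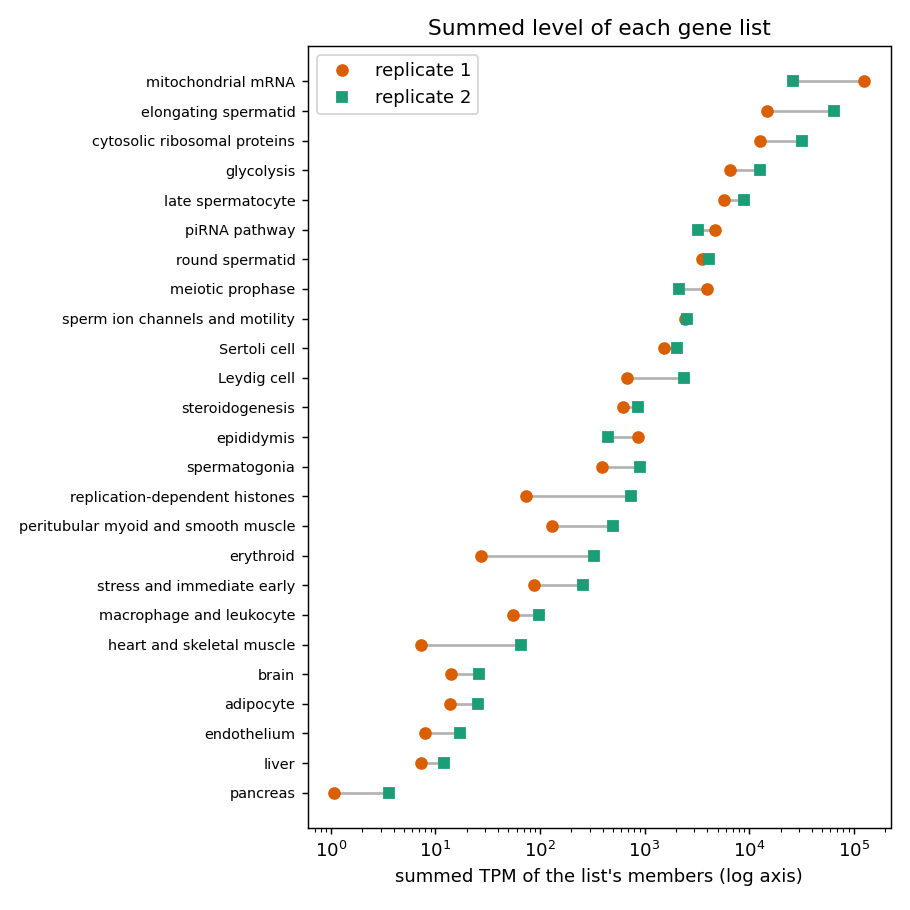
Summed TPM of the members of each of the 25 gene lists (horizontal log axis) in replicate 1 (circles) and replicate 2 (squares), with a line joining the libraries. The elongating spermatid list lies at 14695 and 64861 TPM, second to mitochondrial mRNA in replicate 1 and above every other list in replicate 2.

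Germ cells carry their own copies of several genes whose relatives serve somatic cells, and 12 of 20 such pairs were called higher for the germ cell form in both libraries. The log2 ratios of germ cell over somatic form were 6.77 and 5.68 for Pgk2 over Pgk1, 6.55 and 4.51 for the cytochrome oxidase subunit Cox8c over Cox8a, and 5.11 and 4.82 for Cox7b2 over Cox7b. They were 5.17 and 3.73 for Gapdhs over Gapdh, 3.75 and 4.004 for the pyruvate dehydrogenase subunit Pdha2 over Pdha1, and 3.46 and 3.42 for the ribosomal Rpl39l over Rpl39. Ldhc over Ldha gave 3.32 and 2.32, and the cytochrome c gene Cyct over Cycs 2.54 and 2.53. Lower ratios were found for the ADP/ATP carrier Slc25a31 over Slc25a4 (2.15 and 0.90), Utp14b over Utp14a (2.00 and 0.97), Rpl10l over Rpl10 (1.70 and 1.27) and the chaperone Hspa2 over Hspa8 (0.55 and 1.51). The somatic form was higher in both libraries for 3 pairs. These were enolase (Eno4 over Eno1, -2.69 and -3.69), a cleavage stimulation factor (Cstf2t over Cstf2, -1.37 and -1.72) and the poly(A) binding protein (Pabpc2 over Pabpc1, -2.17 and -1.79). On expected counts without length scaling, the log2 ratio over both libraries was 0.22 for Cyct over Cycs, -0.30 for Cstf2t over Cstf2 and -1.67 for Eno4 over Eno1.

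In 4 pairs the libraries gave opposite directions. Replicate 1 had less and replicate 2 more of Cox6b2 than Cox6b1 (-2.62 and 2.94), of the tubulin Tuba3a than Tuba1a (-0.96 and 3.49) and of Hspa1l than Hspa8 (-0.27 and 0.95), and Aldoart1 over the aldolase Aldoa gave 2.29 and -1.98. Rbmxl2 over Rbmx (0.04 and 2.14) had an interval that included 1 in replicate 1. Across the 20 pairs, the change of the log2 ratio from replicate 1 to replicate 2 correlated with the germ cell form's excess of GC content (Spearman rho 0.82, across pairs, which are not independent replicates).

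**Figure D2:**
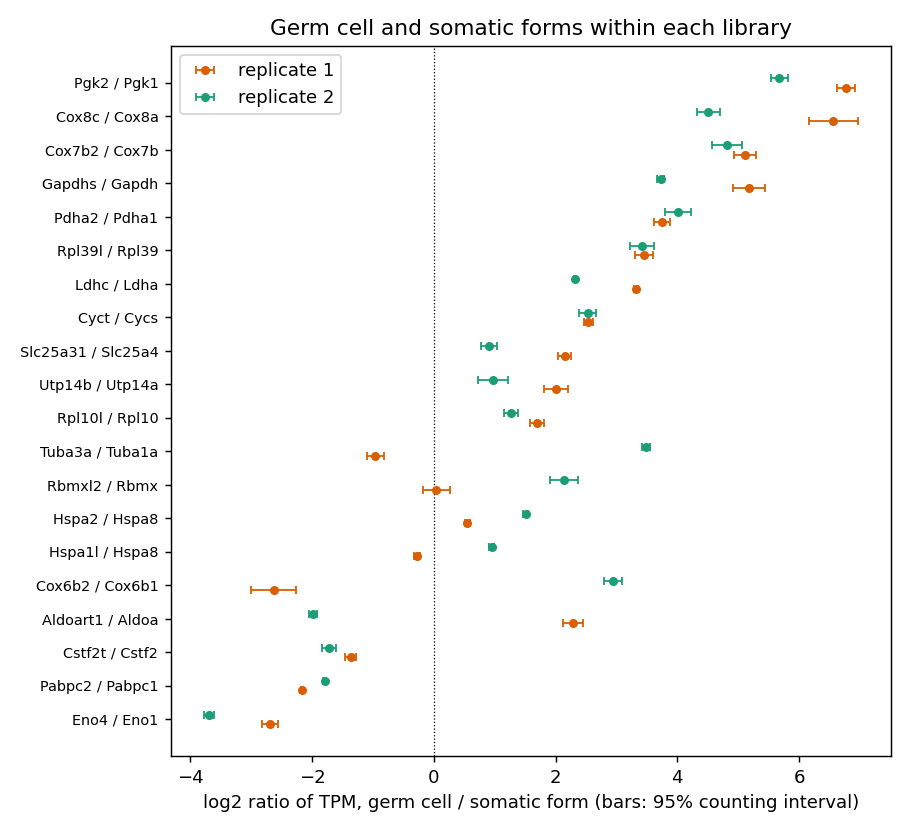
Log2 ratio of TPM of the germ cell form over the somatic form (horizontal axis) for 20 pairs in replicate 1 and replicate 2, with 95% intervals of counting error. With intervals that exclude 0 in both libraries, 12 pairs lie right of 0 and 3 left of it, and 4 pairs lie on opposite sides. Rbmxl2 over Rbmx lies right of 0 in both, with an interval that includes 0 in replicate 1.

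X-linked genes were expressed at lower levels than autosomal genes in both libraries. The median TPM of X-linked protein-coding genes at 1 TPM or more was 0.686 times the autosomal median in replicate 1 (9.10 against 13.3 TPM) and 0.418 times in replicate 2 (7.005 against 16.8 TPM). For the mean of both it was 0.546. None of 10000 random autosomal sets of the same size had a median as low. By mean TPM, 67.9% of 941 X-linked genes and 63.6% of 20337 autosomal genes reached 1 TPM. The median GC content of the X-linked genes was 44.4% against 49.9%. Against autosomal genes of matched GC content, a comparison chosen after seeing the data, the ratio was 0.433 and 0.409. With no lower limit of expression it was 0.868.

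The highest X-linked gene was Akap4 (ENSMUSG00000050089.9, X, 7067519 to 7078609), an anchoring protein of the sperm tail, at 2072 and 1283 TPM. It was followed by the noncoding BC061195 (614 and 312), Tmsb15a (520.4 and 276), 1700003E24Rik (493 and 258) and 4930570D08Rik (342 and 258). On the Y chromosome 82 of 183 protein-coding genes were detected. The translation factor gene Eif2s3y reached 120.4 and 45.2 TPM. Gm29089, Gm21489, Gm20736 and Gm29044 were the other 4 of the 5 highest, at 357 and 64.8, 140.1 and 44.6, 135 and 45.4, and 102 and 41.4 TPM. The most abundant transcripts of Tmsb15a, 4930570D08Rik and Gm29044 are below the labelled size range (299, 196 and 283 bases), so their TPM is uncertain. The posterior SDs of Gm29089 were 259 of 3208 reads and 129 of 376 reads.

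At the level of transcripts, 10694 of 13778 detected genes (77.6%) had the same most abundant transcript in both libraries. Among the 9123 with more than 1 annotated transcript the share was 66.2%. Angiotensin converting enzyme (Ace) was present mainly as the short transcript Ace-202 of 2418 bases, which held 98.8% and 91.04% of the gene's level. Ldhc-201 held 81.05% and 93.9%, Sycp3-201 83.1% and 86.3%, Ddx4-202 96.7% and 96.1% and Akap4-203 73.4% and 72.8%. Prm1, Tnp2, Odf1, Piwil1, Insl3 and Star had 1 annotated transcript each. The libraries split other genes differently. Clu-201 held 9.18% and 97.7% of Clu, and the 632 base transcript Clu-206 held 89.8% and 0.03%. The 254 base transcript Hk1-216 held 76.6% and 7.12% of Hk1, and Hk1-203 held 8.94% and 58.9%. In Crem, Crem-226 held 50.8% and 10.6%, and in Kit, Kit-201 held 66.1% and 43.2%. Such splits are estimates and carry no replicate check across animals.

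Levels agreed only in part between the libraries. Over all 43346 genes, Pearson's r of log2(TPM + 1) was 0.899 and Spearman's rho 0.908, across genes, which are not independent replicates. Over the 13778 genes at 1 TPM or more in both, r was 0.772. Among these genes, the SD of the log2 TPM ratio was 1.21 over 5103 genes of 1 to 10 TPM and 2.00 over 89 genes above 1000 TPM. The requirement of 1 TPM in both libraries limits the ratio that a gene of low level can have. The 2 SDs therefore do not show how the spread depends on expression.

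**Figure D3:**
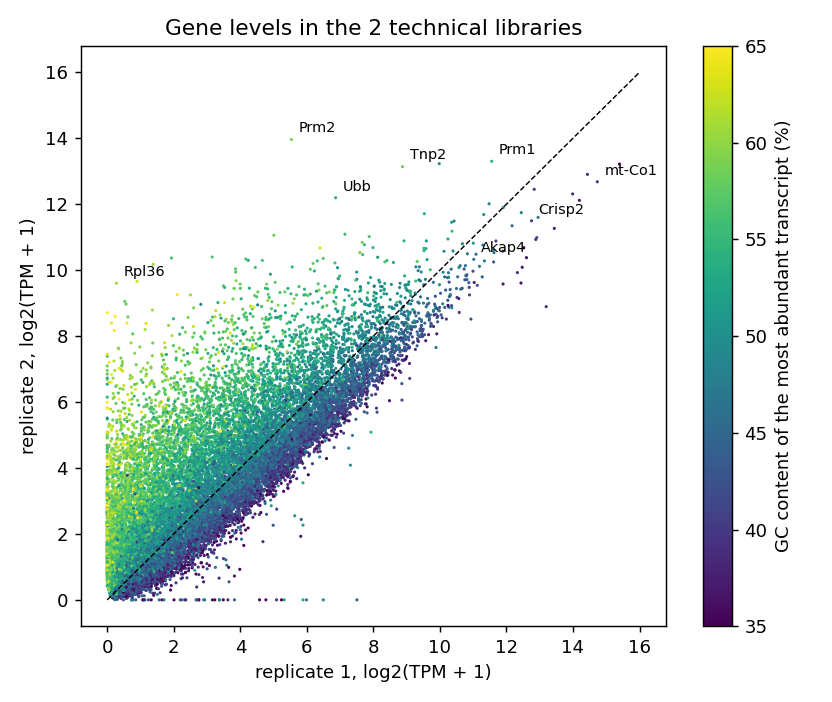
Each point is a gene with a mean of 10 counts or more, plotted by its log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical) and coloured by the GC content of its most abundant transcript. The dashed line marks equal levels, and Prm2 lies far above it at 45.4 against 15928 TPM.

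The libraries differed most in GC-rich transcripts. Of 18581 genes tested, 10363 (55.8%) were called different by the exact binomial test with Benjamini-Hochberg adjustment, 5958 higher and 4405 lower in replicate 2. With plain totals in place of TMM the split was 6717 higher and 2845 lower, because that scaling moves the median of all genes by 0.29 on the log2 scale. The genes higher in replicate 2 had a median GC content of 55.7%, those lower 42.2%, and those not called 48.3%. The log2 ratio rose with GC content over 18396 genes (Spearman rho 0.885, across genes), a relation computed after seeing the data. Its median was -1.99 over 70 genes of up to 35% GC, -0.40 over 5067 genes of 45 to 50% and 4.68 over 628 genes of 60 to 65%. With each gene's expected ratio set by its GC content, a correction added after seeing the data, 3580 of 18396 genes were called, 1973 of them also called in the same direction without it.

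**Figure D4:**
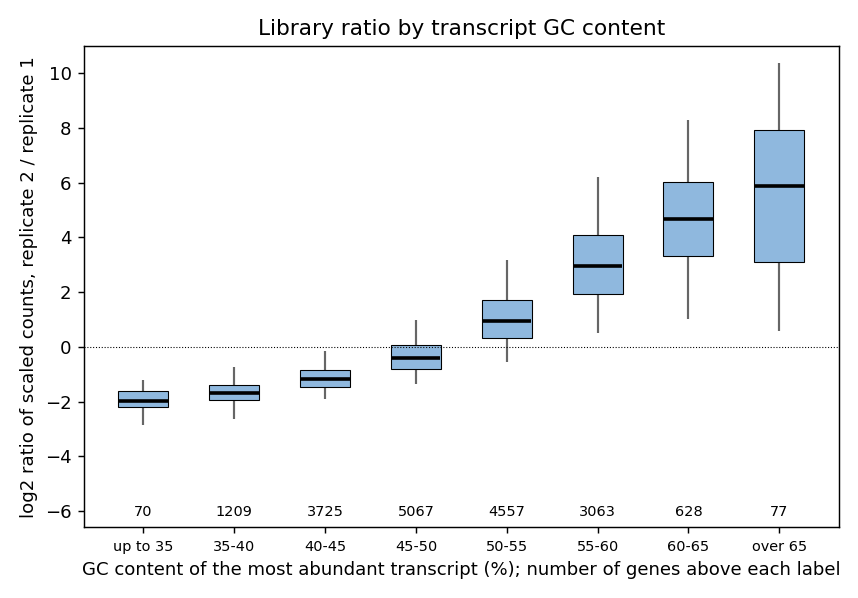
Log2 ratio of scaled counts, replicate 2 over replicate 1 (vertical axis), by GC content of the most abundant transcript (horizontal axis). Boxes span the quartiles around a median line, whiskers the 5th to 95th percentiles, numbers give the genes in each bin, and the median rises from -1.99 in the lowest bin to 5.89 in the highest.

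The 8 genes with the largest ratios towards replicate 2 had a GC content of 54.9 to 70.7%. Fam229a, Zc3h3 and Hist2h2aa1 had 0 counts in replicate 1 and 2205, 1371 and 967 in replicate 2, and Fam229a was at least 929-fold higher there, against 3 counts. The 0 counts of Zc3h3 carried a posterior SD of 26.5, and its fold is uncertain. The ribosomal protein gene Rpl36 had 1 count against 2404, a ratio of 3038 (95% interval 545 to 120054). C1qtnf4 had 1 against 2228, Abhd17a 1 against 1993, Hist2h2aa2 0.64 against 1606 and Tmem239 0.06 against 1064 counts. The posterior SD of Tmem239 in replicate 1 was 12.4, so its difference is uncertain too. Hist2h2aa1 and Hist2h2aa2 are near-identical copies and share reads. The 8 genes with the largest ratios in the other direction had 0 counts in replicate 2. They were the Y-linked Gm21704, Gm28576 and Gm21171, the pseudogenes Gm28439 (a copy of mt-Nd4), Gm4294, Gm15452 and Gm6829, and the noncoding Gm28037. Gm21704 had 994 counts in replicate 1 with a posterior SD of 203, and its 0 in replicate 2 had a posterior SD of 55. Gm6829 had 236 with a posterior SD of 17.4, and its 0 one of 2. No fold is given for these genes. Most of the 8 are members of multicopy families or pseudogenes, and the division of their reads is uncertain.

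Whole gene groups moved with this difference. 7 of 24 lists with 3 or more tested members had a median log2 ratio outside the central 95% of random lists matched on expression. Elongating spermatid genes were higher in replicate 2 (median 2.52, 12 of 18 called higher and 1 lower, median GC 54.1%), with Prm2 at a log2 ratio of 8.12 and Tnp2 at 3.97, while Akap4 was at -1.01. Glycolytic genes (median 2.10, 15 of 21 higher), ribosomal protein genes (median 1.97, 46 of 78 higher and 1 lower) and erythroid genes (median 3.86, 5 of 5 higher) were also higher. Meiotic prophase genes were lower in replicate 2 (median -1.25, 14 of 24 lower and 2 higher, median GC 41.5%), with Sycp3 at -1.93 and Hormad1 at -1.99. So were mitochondrial mRNAs (median -2.54, 13 of 13 lower) and epididymal genes (median -1.38, 3 of 5 lower). Against random lists matched also on GC content, a comparison added after seeing the data, the elongating spermatid, meiotic prophase and epididymis lists fell inside the central 95%, at percentiles 96.5, 27.9 and 14.1. The erythroid, glycolysis, ribosomal and mitochondrial lists lay outside it in this comparison too.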

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

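Entries with purely numeric identifiers, which belong to none of the gene comparisons, held 5 reads in replicate 1 and 0 in replicate 2, and the first number is above the 3 reads that a count of 0 allows. They fell on 2 of the 26248 entries, with 4 reads on 1 of them, and what these entries stand for is not given in the sources used here.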

How the results depend on the processing

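No paired analysis was possible because there is 1 group. The values over genes with more than 1 transcript, with matching on or correction for GC content, and of the correlation with GC content were chosen after seeing the data. At a limit of 5 TPM 8907 genes were detected in both libraries. With each library alone the number detected was 14611 to 16715, the share of TPM in the top 100 genes 21.5 to 35.1%, and the ratio of X to autosomes 0.418 to 0.686. The 100 genes with the largest shares of expected counts, ranked anew, held 17.5% of them. The ratio of X to autosomes was 0.868 with no lower limit of expression. The share of genes with the same top transcript was 76.4% at 10 TPM or more and 66.2% over genes with more than 1 transcript. Pearson's r was 0.916 with a pseudocount of 0.1, 0.864 with 10, and 0.772 over genes at 1 TPM or more in both. The correlation with GC content was 0.903 over genes with a mean of 100 counts or more. Genes called different numbered 8109 to 15464 over other scalings, filters, ratio limits and tests, and 3580 after the GC correction. The lists outside the central 95% numbered 7 under each other scaling, 4 with matching on GC content and 5 after the GC correction. The cause of the other changes was not tested. Among named genes, lists and pairs 357 values kept their call or moved by less than the spread, 12 moved by more, and 6 lost and 1 gained a place outside the central 95%. The spread of list shares and pair ratios was the SD of the 2 libraries. Leaving 1 library out always moves their mean by less than this SD. Such values could not count as moved, and the 357 is no measure of stability for them. No called value changed sign, but 4 values of 4 pairs and 13 of 8 lists that were not called did. A pair counted as called only if both libraries agreed, so leaving 1 library out could not change the sign of a called pair. The 4 pairs were those in which the libraries gave opposite directions. With replicate 2 left out the log2 ratio turned negative for Cox6b2 (from 0.16 to -2.62), Tuba3a (from 1.26 to -0.96) and Hspa1l (from 0.34 to -0.27), and with replicate 1 left out for Aldoart1 (from 0.15 to -1.98). After the GC correction the median of the stress and immediate early list went from 1.44 to -0.42 and that of the Sertoli cell list from 1.06 to -0.04. The difference between libraries needs both and was not recomputed with 1 left out. At these depths counting error was small beside the difference between the libraries.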

Other observations

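Several long intergenic noncoding RNAs were as abundant as the highest meiotic prophase genes, and were named after their values were seen. The highest of this biotype by mean TPM were 4930571K23Rik (chromosome 7, 125368861 to 125371013) at 501 and 701 TPM, 1700008K24Rik (chromosome 17) at 290.5 and 796 TPM, and 1700016P04Rik (chromosome 6) at 680.2 and 285 TPM. Whether the libraries mark strand is not given in the sources used here, so overlap with other genes cannot be ruled out. For the same reason the levels of antisense genes are uncertain, of which 1700027A15Rik (1814 and 1443 TPM) and Gm11837 (1896 and 607 TPM) had higher values.

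The tests below of library size and of shared reads in gene lists were set before their results were seen, and the other tests were chosen after. The design gives no second group, so no biological difference between groups was tested. The first pattern is that 55.8% of tested genes differed between technical libraries of 1 animal. The test already scales for library size, and 55.1% were called after replicate 1 was thinned to the total of replicate 2. Thinning leaves the expected ratios unchanged under that scaling, so its outcome was nearly fixed in advance and cannot decide on library size. A different cell composition of the preparations is argued against as the whole cause, because members of the same cell type list spread by GC content (Spearman rho 0.67 over 145 members of 10 lists). A GC content bias in library making is a candidate explanation for most of it. A trend fitted on odd-numbered autosomes accounted for 70.1% of the variance on even-numbered ones (72.8% the other way). This restates the correlation with GC content already seen over all genes, and it does not show at which step a bias arose. Ribosomal protein levels fell with GC content in replicate 1 (rho -0.55) against 0.21 in replicate 2. This would place the trend in replicate 1 only if their true levels are unrelated to GC content, which was not tested. The ribosomal list also stood apart from genes of like GC content, so these values cannot tell in which library the trend arose.

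The second pattern is that 4 lists stood apart from genes of like GC content: erythroid, glycolysis and ribosomal protein genes higher, and mitochondrial mRNAs lower, in replicate 2. The peritubular myoid and smooth muscle list lay at percentile 95.6 there, and outside the central 95% after the GC correction (98.8) and with matching on GC content and length (97.9). Transcript length bias is argued against, because 4 of 4 lists stayed outside the central 95% of random lists matched on GC content and length. Those random lists were not matched on expression. Reads shared between paralogs or pseudogenes are argued against for 3 lists, which stayed outside when only genes with a posterior SD under 1% of their count were kept. The erythroid list had fewer than 3 such members and stays open, as does a GC bias acting on parts of transcripts, which was not tested.

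The third pattern is that mitochondrial genes fell unevenly, from a log2 ratio of -1.95 to -4.61 among the 7 with a chromosome 1 copy. Reads shared between near-identical copies could produce this: summing each gene with its copy lowered the SD of the log2 ratio from 0.85 to 0.184, around a mean of -2.27. The 6 mitochondrial genes without such a copy had a mean of -2.40. What remains is a fall shared by all 13, which the first pattern covers only in part.

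The ratio of X-linked to autosomal medians differed between the libraries, at 0.686 and 0.418, and lay at 0.433 and 0.409 once autosomal genes were matched on GC content.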
